A study of Mus musculus with 4 samples.

How the data were processed

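The series holds 2 mice, 1 pBIC and 1 pBIC10, each with a gene expression library and a TCR library made from the same spleen cell suspension. Per the labels, suspensions were passed through a 70 µm strainer, red cells were lysed, live GFP-positive and GFP-negative cells were sorted and mixed at 20% and 80%, and 17000 to 19000 cells were loaded for a target of 10000. The labels do not say how the pBIC10 genotype alters Il10, and nothing was assumed about it. GFP is not among the 32285 features of the matrices, so lymphoma cells were recognised by B-cell markers and immunoglobulin segments.

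The deposited matrices hold UMI counts per gene and cell barcode, made by the authors with Cell Ranger from 10x 5' libraries. Cell Ranger 3.0.1 and GRCm39 are named per the submitters' processing notes, while the matrix header names cellranger 5.0.1, and this difference was not resolved. Barcodes had been called as cells before deposit: the lowest total was 500 UMIs in pBIC and 657 in pBIC10, so empty droplets were not available and free RNA could not be modelled from them. The deposited TCR tables hold productive contigs with read and UMI counts, and clonotype tables in which the authors give each clonotype's cell count and its fraction of all cells with a clonotype. These fractions summed to 1 in each library. The pBIC TCR tables held 16837 contigs in 8300 barcodes (median 12 UMIs per contig), 8286 of them in the gene expression matrix, and 1990 clonotypes, and those of pBIC10 held 7543 contigs in 3720 barcodes (median 11), 3715 of them in the matrix, and 1733 clonotypes.

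Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept, 17871 in pBIC and 14667 in pBIC10. Scrublet, as in scanpy 1.11.5 with an expected rate of 0.08, called 314 (1.757%) and 316 (2.154%) of these as doublets at score thresholds of 0.3377 and 0.3119, and they were removed. The libraries were clustered together without batch correction on 2000 variable genes, leaving out immunoglobulin and TCR segments, with 30 principal components, 20 neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). A cluster made mostly of cells of 1 library can therefore reflect that library and not a cell type. Clusters were named from marker lists fixed before the data were examined, as were the gene lists, the rule for named genes and the alternative settings. A name needed 3 markers detected above the other clusters, in at least 5% of cells, and markers among the 10 leading genes where UMI counts were low. A leading gene needed UMIs in 10% of cells, and 10 CPM were added to levels in marker scores. The other clusters stayed unnamed. T-like cells were clustered again and called CD8-like where mean Cd8 was at least 3 times Cd4.

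Some rules were set after clusters had been seen: B-like and plasma-like clusters were merged as B-lineage, and the marker thresholds, the limit on markers of rival classes and the rule for low UMI counts were written then. The rules had unequal effects. A pBIC cluster of 310 cells with low UMI counts was named B-lineage, while a similar pBIC10 cluster of 314 cells and a lymphoma-like pBIC10 cluster of 903 cells, in which Ccl22 counted as a dendritic marker, stayed unnamed.

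For each class, UMI counts were summed over the cells of a library and divided by the class total to give CPM. With 1 library per genotype no test was made. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95% (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). A gene at 0 counts took a floor of 3 counts, and its ratio is a bound. Classes with at least 50 cells in both libraries were compared. Class sums were 53594128 and 42712688 UMIs for B-lineage cells of pBIC and pBIC10, 71025004 and 36285193 for CD8-like cells, 8527126 and 30479597 for monocyte/macrophage-like cells, and 3762523 and 1645265 for dendritic-like cells. Shares of cells with a UMI were also taken after drawing 2000 or 5000 UMIs per cell.

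Named genes were Il10, Il10ra and Il10rb in every class compared, up to 2 members per direction from each list with at least 50 UMIs, and 8 genes per direction in each class. These 8 were ranked by the bound of the counting interval nearest to no difference. They needed at least 100 UMIs over both libraries, and in the library where they were higher at least 30 CPM, UMIs in 5% of cells and 10% of the level of the class with the highest level. Immunoglobulin genes with Jchain, TCR segments, mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes were left out. Some genes that the rule allows are not reported here. List members needed 20 UMIs, and a member counted as higher when its ratio was at least 1.5-fold and its counting interval excluded no difference. The median log2 ratio of a list was set against 10000 random lists of the same size drawn within 20 expression bins, with 400 Poisson draws for its own interval. Members of kinds left out of the draw, such as haemoglobin genes, took the bin of the gene nearest in level. This was corrected after values had been seen, since the percentile had left these members out while the median counted them. Mx1, an interferon response gene, is missing from the features. Which lists lead the report was narrowed after list values had been seen, and the lists of other classes are given as well.

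Lists covered T and NK exhaustion or checkpoint, cytotoxicity, naive or quiescent T, type 1 helper T, MHC class I and class II presentation, co-stimulation, inhibitory ligands and receptors, IL-10 and STAT3 response, alternative and inflammatory macrophage, interferon response, proliferation, NF-kappaB targets, germinal centre B, plasma cell, B-cell receptor signalling and resting mature B genes. Stress genes and erythroid, neutrophil and platelet transcripts served as checks of RNA quality and of free RNA.

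TCR clonotypes were those of the deposited tables, for barcodes with a productive TRB chain, and pBIC was rarefied to the cell number of pBIC10. The dominant immunoglobulin V segment was the most frequent leading segment among B-lineage cells. Clone-carrying cells had at least 10 UMIs of both dominant segments.

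Alternative settings fixed beforehand were a stricter filter (500 genes, 5% mitochondrial UMIs), doublet calls kept, Leiden resolutions of 0.6 and 1.6, clustering without 194 list genes, totals without immunoglobulin, TCR, mitochondrial and ribosomal genes, TMM scaling (edgeR 4.0.16, R 4.3.3), means of per-cell CPM, other UMI minimums for list members, T cells defined by a TRB contig or split by transcripts, and other clonotype definitions. Another 4 alternatives were added after values had been seen. Neighbouring genes were taken from an annotation of an earlier mouse genome build, in which 20651 features were found by symbol. It was used for gene order alone.

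The ratio and interval code was tested on simulated data with 11935 genes: all of the 50 genes set at each of 1.5-fold, 2-fold, 4-fold and 8-fold had an interval excluding no difference, as did 4.54% of the 11735 genes left equal. Counts were drawn with Poisson error alone, for genes of at least 100 expected UMIs and at totals well above those of dendritic-like cells. These shares were not shown for smaller classes, for genes with fewer UMIs or for variation beyond counting error. Plots were drawn with matplotlib 3.10.9.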

Results

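Spleen cells from 1 pBIC mouse and 1 pBIC10 mouse, both female and both carrying a GFP-marked B-cell lymphoma, were profiled by droplet single-cell RNA sequencing. Each mouse gave 1 gene expression library and 1 library enriched for T-cell receptor (TCR) transcripts, 4 libraries in all. Before loading, sorted cells of each spleen had been recombined to 20% live GFP-positive lymphoma cells and 80% live GFP-negative cells, so the sort set the ratio of lymphoma to other cells. The pBIC gene expression library held 18129 barcodes and 166941618 UMIs, with a median of 6235 UMIs per barcode, and the pBIC10 library held 14991 barcodes and 147884282 UMIs, with a median of 5458. Both exceed the target of about 10000 cells given in the labels. After filtering and removal of doublet calls, 17557 pBIC and 14351 pBIC10 cells were used. A productive TRB chain was present in 8145 barcodes of the pBIC TCR library and 3659 of the pBIC10 TCR library. With 1 mouse per genotype there are no replicates, so no test between genotypes was possible, genotype cannot be separated from mouse or tumour, and every 95% interval given here covers counting error only.

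The series asks how IL-10 from lymphoma B cells affects the other cells around a diffuse large B-cell lymphoma, so Il10 (ENSMUSG00000016529), the gene of this immunoregulatory cytokine, was examined first. In B-lineage cells Il10 stood at 32.2 CPM (30.7 to 33.7) in the pBIC library, from 1724 UMIs in 3744 cells, and at 0.538 CPM (0.341 to 0.808) in the pBIC10 library, from 23 UMIs in 1775 cells. The log2 ratio of pBIC10 to pBIC was -5.90 (-6.56 to -5.31). Il10 UMIs were found in 26.1% (24.7 to 27.5) of pBIC B-lineage cells, which had a median of 12728 UMIs, and in 1.24% (0.778 to 1.87) of pBIC10 B-lineage cells, with a median of 24029. Erythroid-like cells, which should lack the gene, gave a background of 3.78% and 2.36 CPM at a median of 21220 UMIs in pBIC, and of 0.949% (0.196 to 2.75) and 1.49 CPM at a median of 21410 in pBIC10, so Il10 in pBIC10 B-lineage cells was not above background. With every cell thinned to 2000 UMIs, which left out 297 pBIC and 28 pBIC10 cells, the shares were 5.83% (5.07 to 6.67) and 0.343% (0.126 to 0.746), and at 5000 UMIs they were 13.3% and 0.328%. The ratio moved to -4.59 with doublet calls kept and to -4.88 as a mean of per-cell CPM.

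Il10 was not restricted to B cells. T-like cells held 63.8% of all Il10 UMIs of the pBIC library and 90.0% of those of the pBIC10 library, against 32.5% and 1.78% in B-lineage cells. Because the sort set the ratio of lymphoma to other cells, these shares describe the libraries and not the spleen. CD8-like T cells reached 45.0 CPM (43.4 to 46.6) in pBIC and 31.4 CPM (29.6 to 33.2) in pBIC10, and Il10 UMIs were found in 14.6% and 14.2% of them, at medians of 6844.5 and 7617 UMIs. After thinning to 2000 UMIs the shares were 5.84% and 5.62%, with 90 and 62 cells left out. Within the CD8-like class, sub-cluster 6 held 49.3% of the pBIC counts at 218.6 CPM and sub-cluster 1 held 63.7% of the pBIC10 counts at 88.5 CPM. Il10 was among the leading genes of sub-cluster 6 and was not left out of this clustering. Its concentration there is therefore no independent evidence of an Il10-rich subset. Monocyte/macrophage-like cells stood at 9.38 CPM (7.44 to 11.7) in pBIC and 1.02 CPM (0.691 to 1.44) in pBIC10, while their cluster 24, led by Ace, Treml4 and Cd300e, stood at 25.3 and 31.97 CPM. In a comparison chosen after these values were seen, Cd3e, a T-cell gene, stood at 204 CPM in pBIC and 20.3 CPM in pBIC10 monocyte/macrophage-like cells, a level at which T-cell RNA would bring 5.69 and 0.537 CPM of Il10. Il10 was 1.65 times (1.20 to 2.24) and 1.89 times (1.11 to 3.12) that level, so T-cell RNA can account for a large part of the class values, and the pBIC10 class value was not above the erythroid-like background. Cluster 24, however, held 53.8% and 38.7% of the class's Il10 UMIs. Its Il10 was 6.10 times (3.75 to 9.72) in pBIC and 45.3 times (11.9 to 177) in pBIC10 the level that T-cell RNA would bring. In clusters 2, 7 and 27 of pBIC it was 1.15 times (0.613 to 2.03), 2.85 times (0.893 to 7.60) and 0.489 times (0.219 to 0.977) that level. Cluster 27 held 804 of the 1736 Cd3e UMIs of the pBIC class. Il10ra, which encodes the ligand-binding chain of the IL-10 receptor, was at 28.9 and 27.5 CPM in B-lineage cells, 177 and 220 CPM in CD8-like cells, 186 and 138 CPM in monocyte/macrophage-like cells and 133 and 136 CPM in dendritic-like cells of pBIC and pBIC10. Il10rb, the shared second chain, was at 41.7 and 33.3 CPM, 81.1 and 38.5 CPM, 107 and 73.3 CPM, and 66.4 and 47.4 CPM in the same classes.

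**Figure D1:**
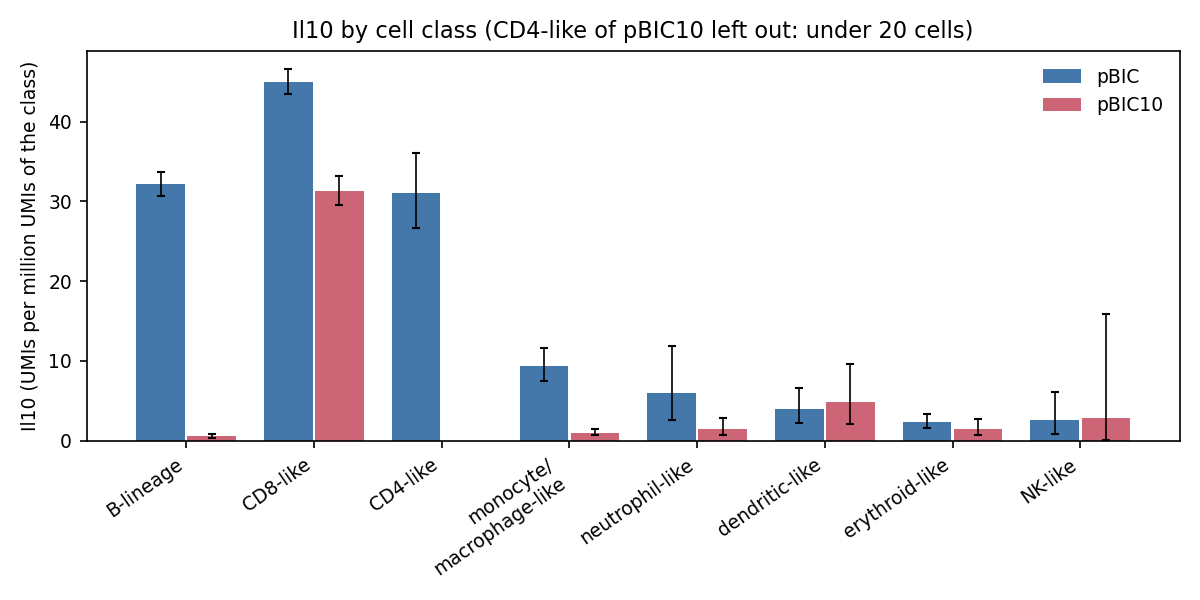
Il10 level (CPM of the class sum) by cell class in the pBIC and the pBIC10 mouse; bars are summed counts of 1 library and error bars are exact Poisson 95% intervals. B-lineage cells stood at 32.2 CPM in pBIC and 0.538 CPM in pBIC10, and CD8-like cells at 45.0 and 31.4 CPM.

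The makeup of the microenvironment differed between the mice. Among named cells outside the B lineage, 11339 in pBIC and 9157 in pBIC10, T-like cells made up 78.0% (77.2 to 78.8) in pBIC and 39.7% (38.7 to 40.8) in pBIC10. Monocyte/macrophage-like cells made up 11.0% (10.5 to 11.6) and 36.3% (35.3 to 37.3), and neutrophil-like cells 2.55% (2.27 to 2.86) and 15.8% (15.1 to 16.6). NK-like cells were at 1.14% (0.951 to 1.35) and 0.240% (0.151 to 0.364), dendritic-like cells at 2.73% (2.44 to 3.05) and 1.76% (1.499 to 2.05), and erythroid-like cells at 4.20% (3.84 to 4.58) and 3.45% (3.09 to 3.85). Small classes were larger in pBIC10: progenitor-like cells at 0.0706% and 0.797%, megakaryocyte-like cells at 0.247% and 1.19%, and basophil/mast-like cells at 0.00882% and 0.710%. No cluster met the markers of plasmacytoid dendritic or stromal cells, although a small plasmacytoid dendritic-like cluster was named at a Leiden resolution of 1.6 and without the list genes. B-lineage cells made up 21.3% of all pBIC cells and 12.4% of all pBIC10 cells. Clusters without a name held 14.1% of pBIC and 23.8% of pBIC10 cells, and those of them that scored highest for B-lineage markers held 10.3% and 20.9%. At a Leiden resolution of 0.6 the difference in NK-like share was -12.98 percentage points against -0.897 and the difference in erythroid-like share changed sign to 0.108; with unnamed cells in the denominator, a choice made after the data were seen, the difference in monocyte/macrophage-like share was 17.4 percentage points against 25.2.

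**Figure D2:**
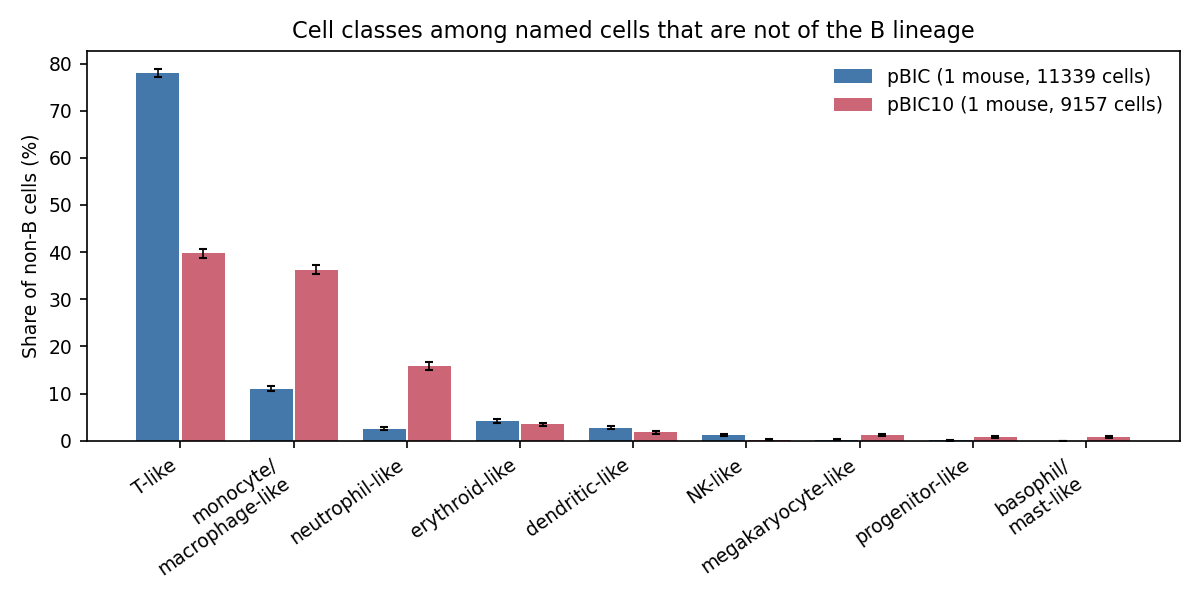
Share (%) of each cell class among named cells outside the B lineage, in the pBIC mouse (11339 cells) and the pBIC10 mouse (9157 cells); error bars are exact binomial 95% intervals. T-like cells were at 78.0% and 39.7%, monocyte/macrophage-like cells at 11.0% and 36.3%, and neutrophil-like cells at 2.55% and 15.8%.

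CD8-like cells dominated the T-like class of both mice. They made up 86.4% (85.7 to 87.1) of the 8846 T-like cells of pBIC and 92.1% (91.2 to 93.0) of the 3639 of pBIC10. A CD4-like cluster held 12.1% (11.4 to 12.8) of T-like cells in pBIC, 1070 cells, and 0.220% (0.0950 to 0.433) in pBIC10, 8 cells. Regulatory T-like (Treg-like) cells, named by Foxp3, the lineage factor of regulatory T cells, were 0.317% (0.210 to 0.457) in pBIC and 3.08% (2.54 to 3.69) in pBIC10, or 28 and 112 cells. Over both mice, this sub-cluster had mean Cd8 at 266 CPM and Cd4 at 131 CPM, so it cannot be read as CD4 cells alone. No gamma-delta-like sub-cluster was found, and 1.15% of pBIC and 4.56% of pBIC10 T-like cells stayed unnamed, among them a pBIC10 sub-cluster of 106 cells led by Igfbp4, Ccr7, Tcf7 and Lef1 with Cd4 and Cd8 transcripts. Because clusters can miss scattered CD4 cells, T-like cells were also split by their own transcripts after thinning to 2000 UMIs, which left out 197 and 115 cells. Cells with Cd4 and no Cd8 UMIs were then 8.07% (7.50 to 8.66) in pBIC and 5.56% (4.83 to 6.37) in pBIC10, cells with Cd8 and no Cd4 UMIs 72.6% and 76.3%, cells with both 1.32% and 0.624%, cells with neither 18.0% and 17.5%, and cells with a Foxp3 UMI 0.393% (0.272 to 0.549) and 1.99% (1.55 to 2.503). The difference in CD4-like share was thus -11.9 percentage points by clusters and -2.51 by transcripts, and the difference in CD8-like share changed sign to -0.632 at a Leiden resolution of 0.6.

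B-lineage cells of each mouse shared 1 dominant light chain V segment, and the main heavy chain constant region differed between the mice. In pBIC, Ighv2-9 was the leading heavy chain V segment in 99.4% (99.1 to 99.6) of the 3512 B-lineage cells with heavy V counts and Igkv8-30 the leading light chain segment in 94.6% (93.8 to 95.3) of 3620 cells. In pBIC10, Ighv9-1 led in 65.2% (63.0 to 67.5) of 1764 cells, Ighv9-3 in 18.6% and Ighv1-11 in 6.58%, and Igkv3-1 led the light chain in 91.0% (89.6 to 92.3) of 1774 cells. Of heavy V segment UMIs in pBIC10, Ighv9-1 took 37.8%, Ighv9-3 31.2% and Ighv1-11 10.2%, so the heavy chain of pBIC10 is uncertain, and CDR3 sequences of B cells were not available. The Ighv9 family together led in 85.0% (83.3 to 86.7) of cells, and 115 of the 116 Ighv1-11 cells carried Igkv3-1. Ighm, the IgM constant region, took 95.8% of heavy constant region UMIs in pBIC B-lineage cells, and Igha, the IgA constant region, took 93.6% in pBIC10. Cells of any class with at least 10 UMIs of both dominant segments, a set defined after the data were seen, had Il10 at 33.4 CPM (31.8 to 35.1) in 2488 pBIC cells and 0.334 CPM (0.167 to 0.597) in 1126 pBIC10 cells.

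B-lineage cells of pBIC10 differed from those of pBIC in immunoglobulin-related, interferon and single co-stimulatory genes. The class held 3744 pBIC and 1775 pBIC10 cells. Another 1816 and 3004 cells in unnamed clusters scored highest for B-lineage markers and are left out of the ratios and list medians given here. Jchain, which joins IgA and IgM into polymers, was 205-fold higher in pBIC10 (5.09 and 1047 CPM). Cd70, the ligand of the co-stimulatory receptor CD27, was 132.9-fold higher and Tnfsf9, a co-stimulatory ligand of T cells, 35.6-fold higher, while the co-stimulatory ligands Icosl and Cd86 were 12.8-fold and 3.33-fold higher in pBIC. In pBIC, Socs3, a feedback inhibitor of STAT3 signalling, was 5.74-fold higher than in pBIC10 and Cr2, the complement receptor of mature B cells, 51.8-fold higher. In that library, however, Socs3 stood at 4.77% of its neutrophil-like level and Icosl at 7.13% of its dendritic-like level. The interferon response list was lower in pBIC10: 11 of its 13 measured genes were at least 1.5-fold higher in pBIC, with a counting interval excluding no difference, and none was higher in pBIC10. However, 8 of the 13 were under 10% of their level in another class.

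The median log2 ratio over all B-lineage genes was -0.31, which TMM scaling moved by 0.30. The gene values below are not adjusted for it. Among the genes that met the naming rule, which leaves out immunoglobulin genes and Jchain, those ranked highest were Onecut2, a homeobox transcription factor, with 2 UMIs in pBIC and 4730 in pBIC10 (log2 11.54, 9.68 to 14.58), Parm1 at 10.77, Cadm1, an adhesion molecule, with 2 and 2271 UMIs (10.48, 8.62 to 13.52), Sntg2, with 2 and 1457 UMIs (9.84, 7.98 to 12.88), Clec2f at 8.66, Cep290 at 7.97 and Bace2 at 7.89. Sprr1a had 0 UMIs in pBIC and 1490 in pBIC10, at least 623-fold higher at the floor of 3 counts (lower bound of log2 8.98). Fer, a tyrosine kinase, had 2104 UMIs in pBIC and 0 in pBIC10, at least 559-fold lower at that floor (bound of log2 -8.83). Fras1 had 3770 and 2 UMIs (-10.55, -13.60 to -8.70) and Kndc1 1879 and 2 (-9.55, -12.60 to -7.69), while Camk2n1 was at -7.80, Fam241b at -7.72, Nav2 at -7.71, Akap12 at -6.90 and Mgmt, a DNA repair methyltransferase, at -6.47. These cells came from different clusters in each mouse, clusters 6, 14, 17, 18, 26 and 30 in pBIC and 9, 21 and 29 in pBIC10.

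Among the lists in B-lineage cells, each median is given as a log2 ratio with its percentile among 10000 random lists of matched expression. The interferon response stood at -2.22 (percentile 0), or -1.91 relative to all genes, with Usp18 9.18-fold and Ifit3 7.76-fold higher in pBIC. Resting mature B genes stood at -2.12 (percentile 0), with 8 of 10 higher in pBIC, although Fcer2a was 12.99-fold higher in pBIC10. The IL-10 and STAT3 response stood at -0.33 (percentile 32.4), or -0.01 relative to all genes, with 6 of 14 genes higher in pBIC (Socs3, and Zfp36 by 3.08-fold) and 3 higher in pBIC10 (among them Arid5a by 2.54-fold). Of the 14, 3 were under 10% of their level in another class, among them Socs3 and Zfp36. Inhibitory ligands and receptors stood at -0.85 (percentile 3.51), with 9 of 11 higher in pBIC, such as Tnfrsf14 by 3.37-fold. B-cell receptor signalling stood at -0.61 (percentile 1.06), with Cd79a 3.27-fold and Syk 3.92-fold higher in pBIC and Blnk (log2 1.32) higher in pBIC10. NF-kappaB targets stood at -0.56 (percentile 2.75), with Ccnd2 8.52-fold and Tnfaip3 5.82-fold higher in pBIC. MHC class I presentation stood at -0.36 (percentile 6.66), with H2-K1 2.31-fold higher in pBIC, and MHC class II presentation at 0.36 (percentile 94.5), with 2 of 10 higher in pBIC10, H2-Ab1 by 1.78-fold and H2-DMb1 by 2.13-fold. Plasma cell genes stood at 0.52 (percentile 98.8), with 4 of 9 higher in pBIC10. Of these 9, 6 were among the markers used to name clusters, as were 5 of the 11 B-cell receptor signalling genes. The percentiles of these 2 lists are therefore not independent of how the class was named. Co-stimulation stood at 0.27 (percentile 93.1), with 4 of 9 higher in each mouse. Germinal centre genes stood at 0.09 (percentile 80.3) and proliferation genes at -0.48 (percentile 3.63), with Mki67 2.73-fold higher in pBIC and Ccnb1 2.45-fold higher in pBIC10. The stress check list stood at -0.41 (percentile 32.4), and the check list of erythroid, neutrophil and platelet transcripts at 0.53 (percentile 98.5), with S100a8 at 24.4 CPM in pBIC and 101 CPM in pBIC10.

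In CD8-like cells, most genes of the cytotoxicity list and of the IL-10 and STAT3 response list, and 8 of 13 interferon response genes, were lower in pBIC10 than in pBIC. Ifng, the gene of interferon gamma, was at 471 CPM in pBIC and 168 CPM in pBIC10 (log2 -1.48, -1.52 to -1.44), and Ccl5, a chemokine of effector T cells, at 31212 and 11240 CPM (-1.47). Cx3cr1, a receptor of cytotoxic effector cells, was 5.31-fold higher in pBIC. Of the 13 cytotoxicity genes, 9 were at least 1.5-fold higher in pBIC and 1, Klrg1, was higher in pBIC10 (1.71-fold), while Prf1, the pore-forming perforin, stood at 313 and 339 CPM. The inhibitory receptors did not move together: of 12 exhaustion or checkpoint genes, Cd38 was 2.997-fold and Cd160 2.85-fold higher in pBIC, Ctla4 was 1.72-fold higher in pBIC10, and 7 of the 12 met neither mark.

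In CD8-like cells the median over all genes was -0.18 and TMM scaling moved it by 0.12. Cytotoxicity had a median log2 ratio of -0.79 (percentile 0.020), or -0.62 relative to all genes, and exhaustion or checkpoint genes one of -0.36 (percentile 8.76), or -0.18 relative to all genes. The exhaustion median was -0.07 as a mean of per-cell CPM. Of the 13 cytotoxicity genes, 5 were among the markers used to name cells, so that percentile is not independent of the naming. The interferon response stood at -1.09 (percentile 0), with 6 of 13 genes under 10% of their level in another class. Those higher in pBIC included Ifit3 by 5.13-fold and Ifit1 by 3.11-fold, and 1 gene was higher in pBIC10, Bst2 by 1.54-fold. Ifit3 and Ifit1 UMIs were found in 3.95% and 4.80% of pBIC CD8-like cells, and in 1.19% and 2.45% of those of pBIC10. Sub-cluster 15, led by Ifit1 and Ifit3, held 1.61% of CD8-like cells in pBIC and 0.0895% in pBIC10. That difference in share enters the Ifit3 and Ifit1 ratios, and how much of them it accounts for was not tested. The IL-10 and STAT3 response stood at -0.82 (percentile 0), with 9 of 14 higher in pBIC, such as Socs3 by 3.17-fold and Pim1, a STAT-induced kinase, by 2.52-fold, and 2 higher in pBIC10, Nfil3 (log2 0.68) and Il1rn by 1.93-fold at 1.71 CPM. Type 1 helper genes stood at -1.12 (percentile 0.010), with 5 of 7 higher in pBIC, while Il12rb2 was 2.65-fold higher in pBIC10. Proliferation stood at -0.62 (percentile 0.19), with 7 of 12 higher in pBIC, among them Top2a by 2.35-fold and Rrm2 by 2.47-fold. Naive or quiescent genes stood at -0.49 (percentile 4.61) and went both ways: Klf2, a transcription factor of quiescent T cells, was 3.89-fold higher in pBIC, and Ccr7, a lymphoid homing chemokine receptor, was 14.6-fold higher in pBIC10.

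Among the genes that met the naming rule's limits on level, share of cells and level in other classes, the ratios in CD8-like cells were highest on the pBIC10 side for Cd70 (log2 6.25, 5.97 to 6.55), Lad1 (5.63), the actin-severing gene Scin (5.498), Utf1 (4.75), Tdh (4.40), Il1r2, the decoy receptor of IL-1 (4.11), Ccr7 (3.87) and the transcription factor Batf3 (3.85). Those on the pBIC side included Cd7 (-4.47, -4.58 to -4.37), Dtx1 (-3.00), the integrin genes Itgad (-2.93) and Itgb7 (-2.80), and the histone genes Hist2h4 (-2.78), Hist1h2ab (-2.49) and Hist1h2ae (-2.48). Il1r2 in these cells reached 17.5% of its level in neutrophil-like cells, and the check list of erythroid, neutrophil and platelet transcripts stood at 1.66 (percentile 100), with S100a9 at 21.0 and 109 CPM, or 0.129% of its level in neutrophil-like cells. The stress check list stood at -0.11 (percentile 57.5), a sign that TMM scaling turned to 0.01. CD8-like cells fell into different sub-clusters in the mice, with 0, 2, 3, 6, 7 and 8 holding most of those of pBIC and 1, 5, 9 and 10 most of those of pBIC10, and CD4-like and NK-like cells were not compared because pBIC10 had 8 and 22 of them, so the regulatory T, type 1 regulatory and follicular helper lists, fixed for CD4-like cells alone, were not computed.

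**Figure D3:**
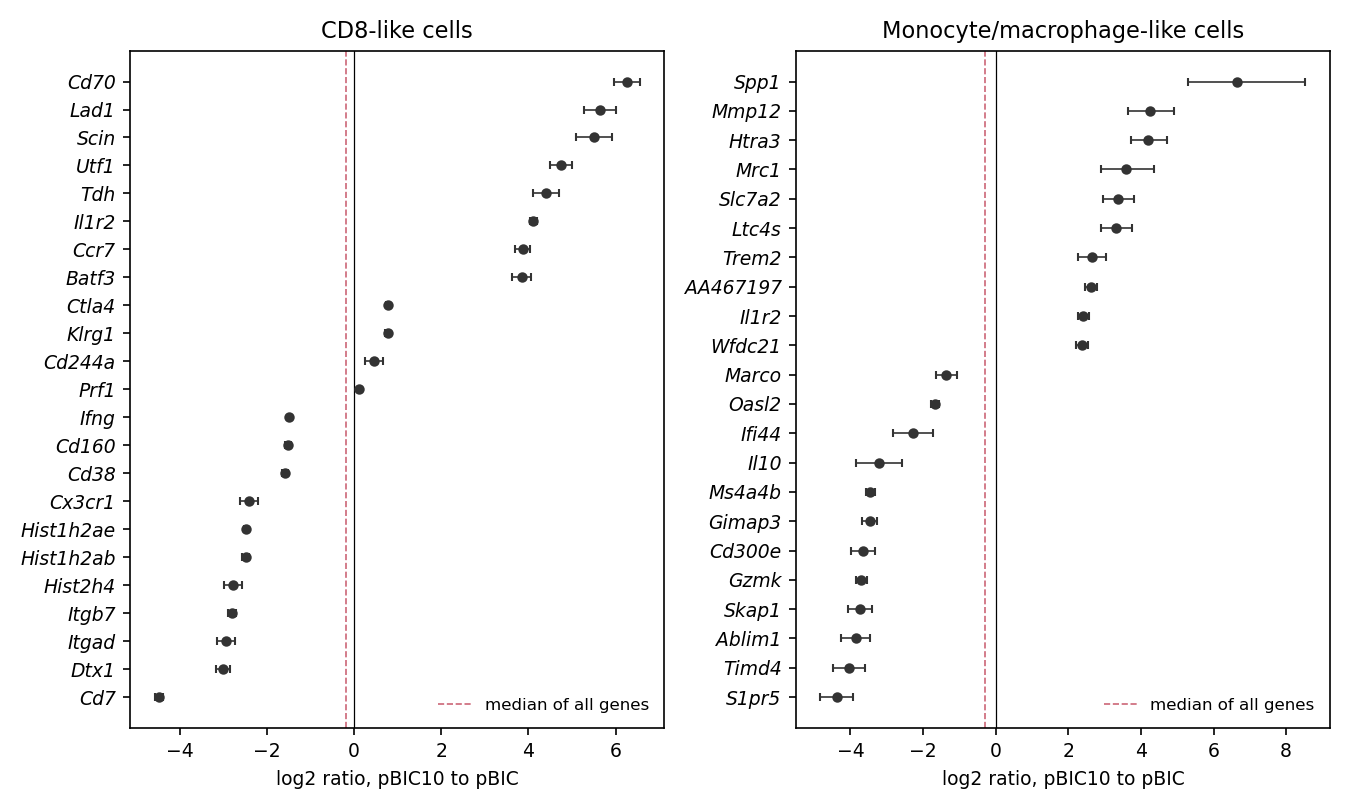
Log2 ratio of pBIC10 to pBIC for named genes in CD8-like and monocyte/macrophage-like cells; points are ratios of summed counts of 1 library each, error bars are exact 95% counting intervals and the dashed line is the median over all genes. Of the genes shown, Cd70 had the highest ratio in CD8-like cells (6.25) and Cd7 the lowest (-4.47); Marco, in the right panel, changed sign when per-cell CPM were averaged.

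Monocyte/macrophage-like cells of pBIC10 had higher levels of 8 of 19 genes of the alternative or suppressive macrophage list and lower levels of 13 of 14 interferon response genes than those of pBIC. Mrc1, the mannose receptor of alternatively activated macrophages, was 11.997-fold higher in pBIC10, Trem2, a lipid-sensing receptor, 6.25-fold higher, and Mmp12, the macrophage elastase, 19.0-fold higher. Spp1, which encodes osteopontin, was 101-fold higher, from 4 UMIs in pBIC and 1441 in pBIC10 (log2 6.66, 5.30 to 8.53), but from few cells. UMIs were found in 3.25% of pBIC10 cells at a median of 8633 UMIs, against 1.30% of pBIC10 B-lineage cells, which should lack the gene, at a median of 24029. The Spp1 level was 57.2% of that in NK-like cells. None of the interferon response genes was higher in pBIC10, and 2 of the 14 were under 10% of their level in another class, with Oasl2 at 142 and 44.7 CPM and Ifi44 at 8.09 and 1.67 CPM. Timd4, a receptor for dying cells on resident macrophages, was 16.3-fold higher in pBIC, and Cd300e, a receptor of patrolling monocytes, 12.5-fold higher. Cd300e was among the leading genes of cluster 24, which held 19.1% of the class in pBIC and 2.56% in pBIC10. That difference in share enters the Cd300e ratio.

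In this class the median over all genes was -0.29, moved by 0.30 under TMM. Alternative or suppressive macrophage genes had a median of 0.23 (percentile 99.6), or 0.52 relative to all genes, with 8 of 19 measured genes higher in pBIC10 and 2 higher in pBIC, Il10 by 9.22-fold, a difference that T-cell RNA and the smaller share of cluster 24 in pBIC10 both enter, and the scavenger receptor gene Marco by 2.57-fold, the second of which changed sign when per-cell CPM were averaged (log2 0.80). Of the 19 genes, 3 were among the markers used to name clusters. The interferon response stood at -1.02 (percentile 0), or -0.74 relative to all genes. The IL-10 and STAT3 response stood at -0.45 (percentile 4.22), or -0.16 relative to all genes, with 6 of 14 higher in pBIC and none in pBIC10, among them Il21r by 2.64-fold and Bcl3 by 1.93-fold. MHC class II presentation stood at 0.16 (percentile 92.1), or 0.45 relative to all genes, with 9 of 10 genes within 1.5-fold and Ciita, the master regulator of the pathway, 1.65-fold higher in pBIC. MHC class I presentation stood at -0.56 (percentile 0.52), with Nlrc5, its transcriptional regulator, 1.96-fold higher in pBIC. Inflammatory macrophage genes stood at -0.28 (percentile 38.9; 0.02 under TMM), with Ccl4 6.44-fold and Ccl3 4.18-fold higher in pBIC, at 7.87% and 8.04% of their T-like levels, and Ccl2 1.88-fold and Cxcl2 1.78-fold higher in pBIC10. Co-stimulation stood at -0.25 (percentile 67.9; 0.05 under TMM and 0.34 from per-cell CPM), inhibitory ligands and receptors at -0.23 (percentile 49.2; 0.07 under TMM), and proliferation at -0.56 (percentile 7.74), with 10 of its 12 genes under 10% of their level in another class.

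The genes ranked highest by the naming rule on the pBIC10 side were Mmp12 (log2 4.25), Htra3 (4.20), the arginine transporter gene Slc7a2 (3.36), the leukotriene synthase gene Ltc4s (3.31), Trem2 (2.64), AA467197 (2.63), Il1r2 (2.42) and Wfdc21 (2.38), with Il1r2 and Wfdc21 at 14.6% and 10.3% of their levels in neutrophil-like cells. On the pBIC side they were S1pr5 (-4.36), Timd4 (-4.03), Cd300e (-3.64) and 5 lymphocyte genes at 12.1% to 15.04% of the level of the class with the highest level, Ablim1 (-3.85), Skap1 (-3.74), Gzmk (-3.70), Gimap3 (-3.47) and Ms4a4b (-3.45). A productive TRB contig was present in 8.55% of pBIC and 1.72% of pBIC10 monocyte/macrophage-like cells. The stress check list was higher in pBIC10 at 0.86 (percentile 100), with 6 of 10 genes higher, such as Egr1 by 3.24-fold and Fos by 2.40-fold, and the check list of erythroid, neutrophil and platelet transcripts stood at 0.97 (percentile 100), or -0.19 with members of at least 100 UMIs, with S100a9 4.84-fold higher in pBIC10 at 0.956% of its neutrophil-like level. The class combined clusters 2, 7, 24 and 27, and cluster 2, led by Tgfbi, Lyz2 and Ly6i, held 31.8% of it in pBIC and 63.9% in pBIC10, while cluster 24 held 19.1% and 2.56%. In pBIC, cluster 27, with 156 cells, held 804 of the 1736 Cd3e UMIs of the class. Its Cd3e stood at 1058 CPM, against 1572 CPM in T-like cells, so it brings much T-cell RNA into the pBIC class sums. In pBIC10 its Cd3e stood at 186 CPM.

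Dendritic-like cells, 310 in pBIC and 161 in pBIC10, formed a single cluster. Ccl17, a chemokine of dendritic cells that attracts T cells, was at 1.59 CPM in pBIC and 522 CPM in pBIC10 (log2 8.35, 7.23 to 9.81), Ccl22, a related chemokine that was also among the naming markers, at 5.58 and 188 CPM (it also led 2 unnamed B-scoring clusters with 1700 and 903 pBIC10 cells and 61 and 1 pBIC cells), and Mgl2, a lectin of type 2 conventional dendritic cells, at 2.66 and 115 CPM. Mmp12 had 0 UMIs in pBIC and 222 in pBIC10, at least 169-fold higher at the floor of 3 counts (lower bound of log2 7.09), and Plet1 (4.82), Fcgr3 (3.69), Epcam (3.45) and C1qa (3.25) followed. Ryr3, a calcium release channel, was 13.7-fold higher in pBIC, Clec4a3 11.4-fold, Dtx1 8.44-fold, Haus8 7.48-fold and Clec4a4 7.13-fold higher, and the histone genes Hist1h2ab, Hist1h2ae and Hist1h1d 7.22-fold, 6.77-fold and 5.64-fold higher. C1qa and Fcgr3 reached 10.5% and 14.97% of their levels in monocyte/macrophage-like cells.

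In dendritic-like cells the median over all genes was -0.29, moved by 0.29 under TMM. MHC class II presentation had a median of 0.34 (percentile 99.7), with H2-DMa 1.58-fold and H2-DMb1 1.62-fold higher in pBIC10 and Ciita 1.64-fold and H2-Ob 1.68-fold higher in pBIC. The interferon response stood at -0.81 (percentile 0.18), with 6 of 13 genes higher in pBIC, such as Usp18 by 2.94-fold, none in pBIC10, and 4 of 13 under 10% of their level in another class. Its median was thus lower in pBIC10 in every class compared. Such a shared difference can come from the library or mouse as well as from each class, and no test was made between these. The IL-10 and STAT3 response stood at -0.46 (percentile 8.02), with 6 of 14 higher in pBIC, among them Il1rn by 2.70-fold, and Socs1 2.19-fold higher in pBIC10. Inflammatory genes stood at 0.14 (percentile 98.0), with 3 of 10 genes higher in pBIC10 and 2 in pBIC, inhibitory ligands and receptors at 0.10 (percentile 96.6), with Cd274, which encodes PD-L1, 1.79-fold higher in pBIC, and co-stimulation at 0.00 (percentile 88.8). Proliferation stood at -0.68 (percentile 0.13), with 7 of 12 higher in pBIC, the stress check list at 0.13 (percentile 96.0), and the check list of erythroid, neutrophil and platelet transcripts at 0.10 (percentile 92.55).

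**Figure D4:**
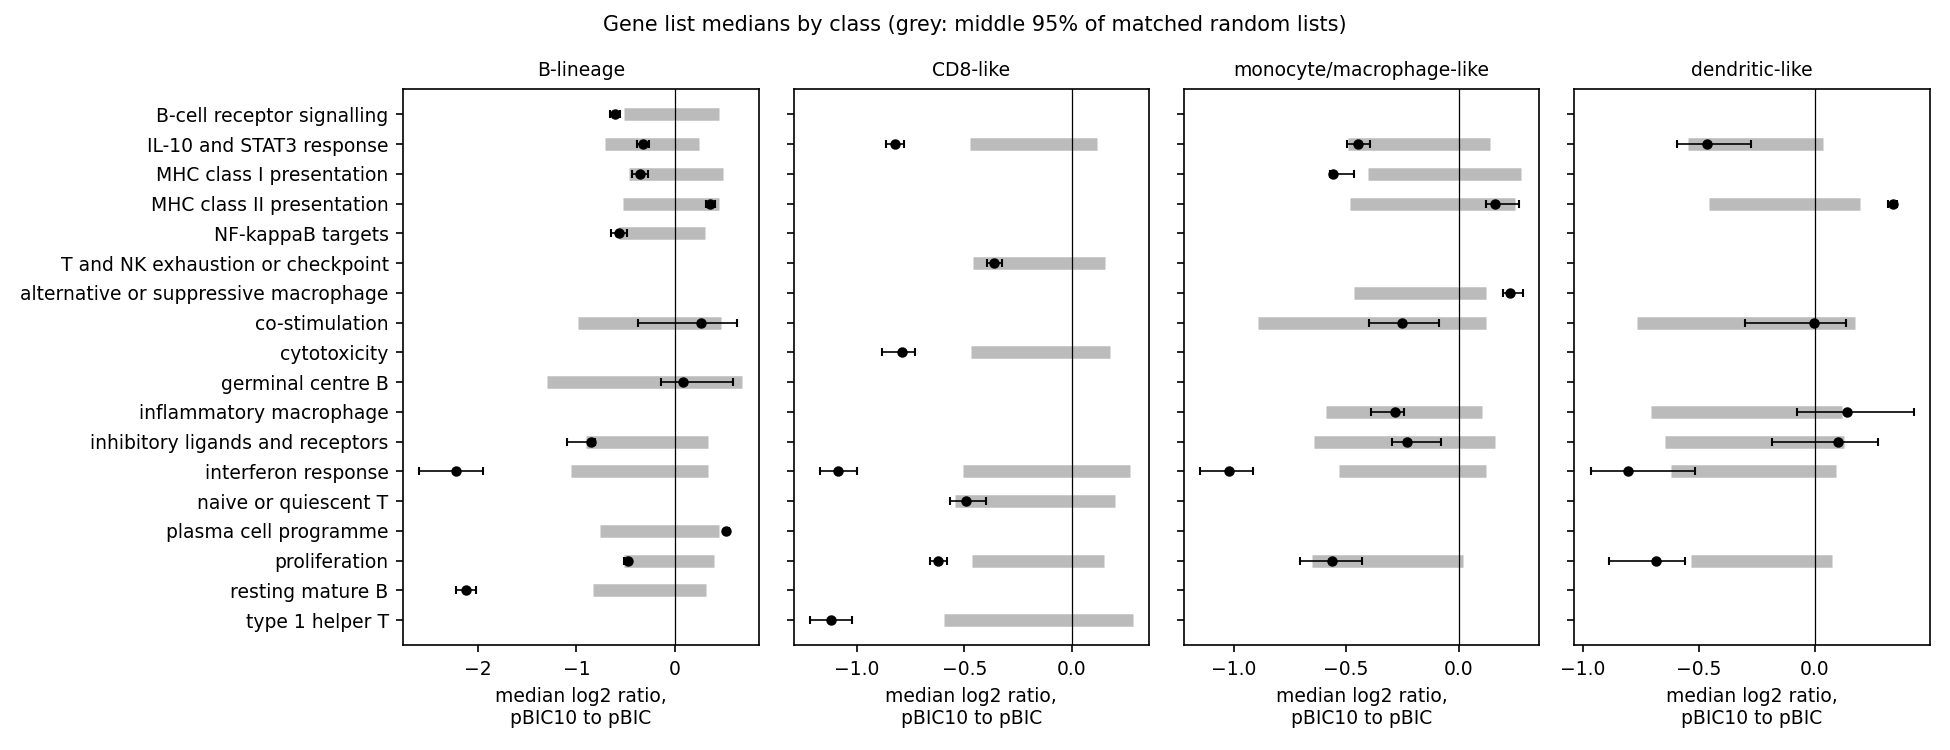
Median log2 ratio of pBIC10 to pBIC of each fixed gene list in 4 cell classes; points are medians over measured genes with 95% counting intervals, and grey bars span the middle 95% of random lists of matched expression. The interferon response lay below the grey bar in all 4 classes, at -2.22, -1.09, -1.02 and -0.81 from left to right. The 4 classes come from the same 2 libraries, so a shared difference can come from the library or mouse as well as from each class. The monocyte/macrophage-like points for co-stimulation, inhibitory ligands and inflammatory genes change sign under TMM scaling, as does the dendritic-like point for co-stimulation.

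T-cell clones were more expanded in the pBIC mouse. Of 8144 pBIC cells with a TRB chain and a clonotype, 85.5% (84.7 to 86.3) belonged to clonotypes of 2 or more cells, against 65.8% (64.2 to 67.3) of 3658 pBIC10 cells. The pBIC cells formed 1921 clonotypes and the pBIC10 cells 1701. When pBIC was rarefied to 3658 cells, its expected values were 1165 clonotypes and 79.8% of cells in expanded clonotypes, so that the order held at equal numbers of cells; reads and UMIs were not equalised. The largest clonotype held 334 cells in pBIC, 4.10% (3.68 to 4.55), and 115 cells in pBIC10, 3.14% (2.60 to 3.76), and the 10 largest together held 18.0% and 13.9%. The effective number of clonotypes, the inverse of the Simpson index, was 175 and 298. Among cells with exactly 1 TRA and 1 TRB chain, the order of the largest clonotype turned to 2.43% in pBIC and 4.04% in pBIC10, the 10 largest held 16.6% and 15.8%, and the effective number was 201 and 225.

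Most cells of expanded clonotypes were CD8-like, 5513 in pBIC and 2080 in pBIC10. Of all CD8-like cells, 83.5% in pBIC and 90.1% in pBIC10 carried a TRB chain. Of those with a chain, 86.4% (85.5 to 87.2) in pBIC and 68.8% (67.1 to 70.5) in pBIC10 belonged to expanded clonotypes, and 288 of the 334 cells of the largest pBIC clonotype and 106 of the 115 of the largest pBIC10 clonotype were CD8-like. Among pBIC CD4-like cells with a TRB chain, 80.8% (78.0 to 83.3) were in expanded clonotypes. In Treg-like cells the shares were 16.7% (4.74 to 37.4) of 24 cells in pBIC and 34.7% (25.4 to 45.0) of 98 cells in pBIC10. The mice had 33 TRB CDR3 amino acid sequences in common, out of 1721 and 1653, and 2 nucleotide sequences out of 1748 and 1674.

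**Figure D5:**
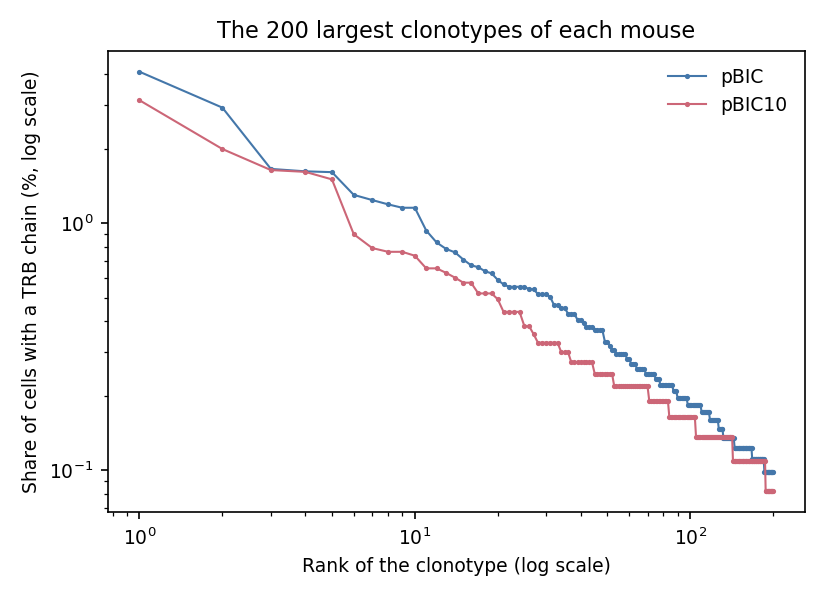
Share (%) of cells with a TRB chain held by each of the 200 largest clonotypes of the pBIC and the pBIC10 mouse, by rank; both axes are logarithmic and each point is 1 clonotype. The largest clonotype held 4.10% of pBIC and 3.14% of pBIC10 cells.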

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

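Of the tests in this part, the comparison of Il10 with Cd3e in B-lineage cells and the 2 later tests of free RNA in CD8-like cells were chosen only after the result was seen.

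T-cell receptor chains were found outside the T-like class. A productive TRB contig was present in 7.59% (6.76 to 8.48) of pBIC and 2.76% (2.05 to 3.63) of pBIC10 B-lineage cells, and in 8.55% (7.06 to 10.2) of pBIC and 1.72% (1.30 to 2.22) of pBIC10 monocyte/macrophage-like cells. The higher shares lie in the library with more T-like cells. Doublets that were not called and free RNA were not told apart here. In addition, the clonotype tables mark 6 pBIC cells and 1 pBIC10 cell with evidence of invariant NKT receptors on both chains.

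Il10 in B-lineage cells of pBIC was set against T cells or their free RNA, since T-like cells held more Il10 than B-lineage cells. Cd3e, a T-cell gene, stood at 71.3 CPM in these B-lineage cells and at 1572 CPM in T-like cells, 4.54% of the T-like level, while Il10 reached 73.2% of it. Il10 was 16.1 times (14.3 to 18.2) the level that Cd3e would bring, which argues against T cells or their RNA as the main source. Expression of Il10 by the lymphoma cells remains as a hypothesis, and what in the pBIC10 mouse accounts for the low level was not tested.

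The larger summed share of monocyte/macrophage-like and neutrophil-like cells in pBIC10, 13.6% against 52.1% or 38.5 percentage points (37.3 to 39.7), was set against 2 technical explanations. Among barcodes with at least 2000 UMIs the difference was 37.3 points (36.0 to 38.5), which argues against barcodes with few UMIs. Counting the 76 unnamed pBIC10 cells with a TRB contig as T-like left 38.1 points (36.9 to 39.3), which argues against T-like cells lost to unnamed clusters. Unequal recovery of cell types in the sort, mouse and genotype stay open, because each is the same split of 1 mouse against 1 mouse.

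The CD8-like differences were measured as the median absolute log2 ratio of 41 named genes, 1.67 over all cells. With 1 cell per clonotype, 1548 and 1380 cells, it was 1.73 (1.63 to 1.84 over 100 draws). Without the 3 dividing sub-clusters, 19.5% of pBIC and 12.1% of pBIC10 cells, it was 1.72. These values argue against a few large clonotypes and against dividing cells as the whole cause of this median. A median can hold while some of its genes fall, and many of the 41 were picked for large ratios in these cells. Single genes, such as the histone and proliferation genes among the 41, were therefore not assessed, nor were other genes. For free RNA the outcome was mixed. The criterion written beforehand was whether another class reaches the CD8-like level for more than 50% of the genes, and it came out on the side of free RNA, at 73.2% (57.1 to 85.8; 30 of 41). That criterion was too broad, since a high level in another class does not mean that its free RNA reaches that level in CD8-like cells. A test chosen afterwards used the level that the markers of the other class reach in CD8-like cells: 97.6% of the genes (87.1 to 99.9; 40 of 41, all but Cd244a) were above 2 times that level. Of these, 16 had been picked by a rule that asks for a minimum level and could not fail. Among the other 25 genes it was 24, or 96.0% (79.6 to 99.9). Each gene was set against 1 other class alone, the one with the highest level. For some genes the markers of that class hardly reach CD8-like cells, such as megakaryocyte-like for Ifng (0.00308%) and neutrophil-like for Socs3 (0.0277%). Free RNA of the other classes and of unnamed cells was not assessed. The later tests therefore speak only against free RNA of the class with the highest level. A T-cell difference between the mice stays a hypothesis.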

How the results depend on the processing

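Of the results that answer the series' question, 126 values under the alternatives fixed beforehand stayed the same, 61 moved and 2 changed direction; of the values of the 4 alternatives added after values had been seen, 8 stayed the same and 6 moved. Among the other results 1580 values stayed the same, 537 moved and 18 changed direction. These include 1805 values of 226 named genes, 10 of them counted as reversed, and 330 values of 33 lists, 8 of them counted as reversed. The counts leave out some values near no difference that also turn under TMM scaling, such as Il10ra in B-lineage cells and co-stimulation in dendritic-like cells. The cause of each shift was not tested. No paired analysis was possible because each genotype has 1 library of each kind. The alternative that took the T-like barcodes alone for clonotypes moved no value of the clonotype results, and the list member minimums of 1 and 100 UMIs moved no list that answers the question. Il10 in B-lineage cells (log2 ratio -5.90) was -5.31 with the unnamed clusters that score highest for B cells, and the difference in dendritic-like share (-0.976 percentage points) moved under none of the alternatives run.

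With doublet calls kept, Il10 in B-lineage cells was -4.59, the difference in neutrophil-like share 14.5 percentage points against 13.3, in NK-like share -2.38 against -0.897, in CD8-like share of T-like cells 3.86 against 5.71 and in CD4-like share -10.5 against -11.9. List medians moved to -0.25 for the IL-10 and STAT3 response in B-lineage cells (-0.33), -1.89 for the interferon response in B-lineage cells (-2.22) and 0.30 for alternative macrophage genes (0.23), and the dominant light V segment of pBIC10 to 88.4% from 91.0%.

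With the stricter cell filter, the difference in CD8-like share was 9.53 points, the IL-10 and STAT3 response in B-lineage cells -0.25, the dominant heavy and light V segments of pBIC 98.97% against 99.4% and 92.9% against 94.6%, and the light V segment of pBIC10 88.2%.

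At a Leiden resolution of 0.6, the difference in erythroid-like share turned to 0.108 points from -0.747 and that in CD8-like share to -0.632. The difference in T-like share was -25.98 against -38.3, in NK-like share -12.98 and in CD4-like share -4.84. The IL-10 and STAT3 response in B-lineage cells was -0.24, exhaustion in CD8-like cells -0.41 against -0.36, and the dominant V segments of pBIC10 67.8% against 65.2% (heavy) and 88.01% (light). Tyms in CD8-like cells turned to -0.0279. At 1.6, the difference in NK-like share was -2.36, the IL-10 and STAT3 response in B-lineage cells -0.43 and the dominant V segments of pBIC10 60.03% and 93.4%.

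Clustering without the list genes gave -1.92 points for NK-like, -0.00809 for erythroid-like and 8.56 for CD8-like shares and 62.03% for the heavy V segment of pBIC10, and Cxcl10 in dendritic-like cells turned to -0.14. T cells defined by a TRB contig gave -29.98 points. T-like cells split by transcripts gave 3.66 points for CD8, -2.51 for CD4 and 1.59 against 2.76 for Treg.

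The added alternatives gave, with unnamed cells in the denominator, -35.1 points for T-like, 17.4 against 25.2 for monocyte/macrophage-like and 9.44 for neutrophil-like cells. With barcodes of at least 2000 UMIs they gave -36.5 for T-like and 12.2 for neutrophil-like cells. Cells with both dominant V segments gave -6.64 for Il10.

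Under TMM scaling, medians were -0.0261 (IL-10 and STAT3 response) and -1.92 (interferon response) in B-lineage cells, -0.24 (exhaustion), -0.67 (cytotoxicity), -0.70 (IL-10 and STAT3) and -0.97 (interferon) in CD8-like cells, and 0.46 (MHC class II), -0.15 (IL-10 and STAT3), 0.53 (alternative) and -0.72 (interferon) in monocyte/macrophage-like cells. Direction turned for the stress list in CD8-like cells (0.00864), for co-stimulation (0.0489), inhibitory ligands (0.0686) and inflammatory genes (0.0169) in monocyte/macrophage-like cells, for H2-DMb2 (0.0744) and Sec11c (0.0523) in B-lineage cells and for Jun in dendritic-like cells (0.0116). Some values whose own interval spanned no difference turned as well and were not counted. Among them were Il10ra and Hbb-bt in B-lineage cells (-0.07 and -0.10 before TMM) and H2-Oa and Dnajb1 in monocyte/macrophage-like cells (both -0.013). Co-stimulation in dendritic-like cells (-0.0013) was another.

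With totals that leave out immunoglobulin, TCR, mitochondrial and ribosomal genes, medians were -0.26 for the IL-10 and STAT3 response in B-lineage cells, -0.20 (exhaustion), -0.63 (cytotoxicity), -0.66 (IL-10 and STAT3) and -0.93 (interferon) in CD8-like cells, and -0.38 (IL-10 and STAT3) and 0.30 (alternative) in monocyte/macrophage-like cells, and the stress list in CD8-like cells turned to 0.0493. It also turned with members of at least 1 UMI (0.0148), and the list of erythroid, neutrophil and platelet transcripts in monocyte/macrophage-like cells turned to -0.19 with members of at least 100 UMIs.

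As means of per-cell CPM, Il10 in B-lineage cells was -4.88, and medians were -0.24 (IL-10 and STAT3) and -1.59 (interferon) in B-lineage cells, -0.0710 (exhaustion) and -0.95 (interferon) in CD8-like cells, and 0.61 (alternative) and -0.78 (interferon) in monocyte/macrophage-like cells. Direction turned for co-stimulation (0.34), Marco (0.80) and Socs1 (-0.0195) in monocyte/macrophage-like cells, Jun in CD8-like cells (-0.48), and S100a8 (0.66) and S100a9 (0.91) in dendritic-like cells.

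Clonotypes by TRB CDR3 alone gave 88.4% and 68.2% of cells in expanded clonotypes in pBIC and pBIC10, against 85.5% and 65.8%. With exactly 1 TRA and 1 TRB chain the largest clonotype held 2.43% and 4.04%, against 4.10% and 3.14%.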

Other observations

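The genes of this paragraph and the next were chosen after their values had been seen. Gzmb and Gzmk were the granzyme genes with the highest levels in CD8-like cells of both mice, and 5 other granzyme genes were found almost only in pBIC10. Gzme had 1 UMI in pBIC and 3934 in pBIC10 (log2 12.91, 10.43 to 18.22), Gzmd 0 and 2324 (log2 of at least 10.57 at the floor of 3 counts, bound of the counting interval 10.27) and Gzmg 0 and 816 (at least 9.06, bound 8.75), and Gzmf (5.42) and Gzmc (4.98) were higher in pBIC10 as well. These 5 stood at 6.39% (Gzme) or less of their level in the 22 NK-like cells of pBIC10, so they fell outside the limits of the naming rule, and none passed 2 times the 4.60% that NK-like markers reach in CD8-like cells. Free RNA would reach all cells of a library, however, and T sub-cluster 5, with 913 pBIC10 cells and 0 pBIC cells, held 89.8% of the CD8-like Gzme UMIs at 15.6% of the NK-like level, against 0.295% of that level in sub-cluster 1 of the same library. Gzme also leads sub-cluster 5, and granzyme genes were not left out of the clustering. The concentration is therefore no independent evidence on free RNA. By contrast, Gzma (247 and 90.1 CPM), Gzmb (2991 and 1093 CPM), Gzmk (1407 and 842 CPM) and Gzmm (9.50 and 4.91 CPM) were higher in pBIC. Tff1 (3.40), Serpine2 (2.70), Penk, which encodes proenkephalin (2.12), Il2ra, the high-affinity IL-2 receptor chain (2.42), and Tnfrsf4, the co-stimulatory receptor OX40 (1.07), were higher in pBIC10. The CD4-like cells of pBIC, whose cluster had no counterpart of size in pBIC10, expressed Gzmk at 1888 CPM, Ccl5 at 32430 CPM, Maf at 352 CPM, Ifng at 284 CPM, Eomes at 250 CPM, Pdcd1 at 223 CPM, Lag3 at 108 CPM and Il10 at 31.1 CPM (26.7 to 36.0), with Cd40lg at 18.1 CPM, Il21 at 4.52 CPM and Foxp3 at 1.74 CPM.

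Transcripts of 66 histone genes were higher in pBIC in each of 6 classes. The sum was 4.97-fold higher in B-lineage cells (2560 and 515 CPM), 3.99-fold in CD8-like, 3.98-fold in dendritic-like, 3.30-fold in monocyte/macrophage-like, 3.13-fold in erythroid-like and 1.47-fold in neutrophil-like cells. Mki67, a gene of dividing cells, was higher in pBIC in 5 of these classes and stood at 149 and 180 CPM in neutrophil-like cells. A difference shared by unrelated classes can come from the library as well as from the cells, and no test was made between these.

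Neighbouring genes led the pBIC10 lymphoma clusters together. Around Psmg3, the 18 measured genes within 15 gene places, leaving out those that lead a cluster, had a median B-lineage log2 ratio of 2.01, at percentile 99.9 of stretches of as many genes, with Mafk at 3.54, Gna12 at 3.18 and Chst12 at 3.16 and with Lfng (-2.61) and Sun1 (-0.36) as exceptions. In CD8-like cells the median over 17 genes was 0.08, at percentile 93.3. Around Gstt1 the median over 16 genes was -0.43, at percentile 35.9. The criterion written beforehand took such a value as evidence against a gain, but it left out the genes that lead clusters, so a gain confined to these stays open and the test excludes nothing. A gain of DNA copies around Psmg3 in the pBIC10 lymphoma is a hypothesis, and shared regulation of the stretch may give the same values. DNA was not measured.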
